A study of Homo sapiens with 16 samples.

How the data were processed

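RNA sequencing was read from 16 libraries of HEK293T cells: 12 pull-downs and 4 inputs. Per the labels' protocols, cells were given AC-2 at 50 µM for 3 min, 24 h after transfection with a BS2 construct, and labelling was stopped with PMSF. RNA was clicked to biotin, enriched, selected by poly(A) and made into libraries with a KAPA mRNA HyperPrep kit. Poly(A) capture limits what can be seen of RNAs without a tail.

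The deposited table holds log2 values of normalized CPM, which the design fixed in advance had assumed to be plain CPM. Per the submitters' processing notes, reads were handled with STAR 2.7.9a, Salmon 1.4.0 and limma on GRCh38, without a role or order for each. Per the labels, the values are filtered and TMM normalized. The table has 39823 entries, of which 14906 carry no value in any library. Of the 24917 others, 39 names occur more than once with identical values, and keeping each once left 24878 genes, 17618 of them protein-coding and 7120 of them lncRNAs. Every library has the same lowest value, -2.5907, which is the log2 of 0.166, so CPM was taken as 2 to the deposited log2 value minus that constant. Values fell on whole multiples of a smallest step (tolerance 0.01) in 73.7% to 87.5% of cases by library, and low values in 76.7% to 88.4%, too few for a count-based test.

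The step gave depths of 6.34 to 20.0 M reads (M for mega), so that 1 read stood for 0.0541 to 0.154 CPM. A level of 0 in a group was replaced by 3 reads when a lower limit of a fold was given. Such limits cover counting error alone. Coordinates come from GENCODE 29 on GRCh38, matched by gene identifier for 24064 of 24878 genes (96.7%). Transcript length and GC content come from the same annotation. Both are medians over the annotated transcripts of a gene, which need not match the form expressed.

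Groups followed the labels: non-transfected (3 pull-downs), cytosolic (2), nuclear (3), mitochondrial (2) and nucleolar BS2 (2), and 4 inputs of 1 library each. Genes with at least 1 CPM in at least 2 libraries were fitted as log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (trend on, Benjamini-Hochberg adjusted p < 0.05), in a fit of all pull-downs, with the inputs added where a comparison uses them. There were 11 comparisons: 4 constructs against non-transfected, 3 between constructs, pull-down against input with construct as covariate, and 3 input-corrected differences. Inputs without replicates were assumed to vary like the pull-downs. The comparisons, tests, thresholds, named-gene rule, list tests and most alternatives were chosen before the data were examined.

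Named genes were the 10 largest rises and 10 largest falls among genes with adjusted p < 0.05, no overlap between the groups and a mean of at least 5 CPM in the higher group. Genes known only by a clone name were counted but not named. With fewer than 5 such genes the 5 smallest p-values were added. Up to 4 members per list, MALAT1, NEAT1 and the 13 mitochondrially encoded mRNAs could always be named, and the text gives a selection.

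The 21 lists were mitochondrially encoded mRNAs, mitochondrial ribosomal and transfer RNAs, nuclear-encoded oxidative phosphorylation subunits, mitoribosomal proteins, cytosolic ribosomal proteins, nuclear-retained lncRNAs, cytosolic lncRNAs, detained-intron mRNAs, ZNF zinc finger mRNAs, small nucleolar and small Cajal body RNAs, nucleolar and polymerase III RNAs, spliceosomal small nuclear RNAs, nucleolar protein mRNAs, replication-dependent histones, ER and secretory mRNAs, heat shock genes, stress and unfolded protein response genes, interferon genes, immediate-early and short-lived mRNAs, cytosolic housekeeping mRNAs and markers absent from HEK293T. Members were written from general knowledge. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Members were also counted among genes passing over all genes and after adjustment over the list alone.

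Alternatives were CPM rescaled to a common total, the same without mitochondrially encoded genes, median-of-ratios scaling, quantile normalization, other pseudocounts and filters, robust moderation, no trend, other sets of libraries in the fit, replicate numbers as a block, a minimum 2-fold change, and each library left out in turn. Added later were the deposited log2 values as they are, removal of a length and GC trend, voom on rounded reads, and removal of genes at least 4-fold higher in a transfected input. Shared controls were addressed with 50 simulations of unchanged groups.

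The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Changed genes were drawn from those with a mean level of at least 5 CPM in the non-transfected pull-downs. Noise was normal, independent between libraries and set at the fitted spread. Recovery at lower levels and shifts of a whole library were therefore not tested. Against non-transfected, 96% to 99% of 2-fold changes were called among 15019 genes, and between constructs 94% to 96% among 15046. Pull-down against input gave 99% among 15081 genes, and the input-corrected differences 50% to 56% among 15114. False calls were 5 to 16 per comparison. Levels of XIST, TSIX and Y-linked genes were left out.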

Results

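RNA near a targeted enzyme was labelled in living HEK293T cells, a human embryonic kidney line, and sequenced. Cells expressed BS2, an esterase, targeted to the cytosol, the nucleus, the mitochondria or, through a NIK3x tag, the nucleolus. BS2 unmasks the probe AC-2, and the labelled RNA was clicked to biotin, pulled down, captured by its poly(A) tail and sequenced. Non-transfected cells given the same probe were the background. There were 12 pull-down libraries: 3 non-transfected, 2 cytosolic, 3 nuclear, 2 mitochondrial and 2 nucleolar. The 4 input libraries, taken without pull-down, were 1 each for non-transfected, cytosolic, nuclear and mitochondrial cells, so no value of a single input has a replicate. No nucleolar input was used here.

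Depth, estimated from the smallest step between values, was 13.3, 8.002 and 10.7 M reads (M for mega) in the non-transfected pull-downs and 11.2 and 13.02 M in the cytosolic ones. It was 9.45, 11.1 and 11.9 M in the nuclear, 20.01 and 10.7 M in the mitochondrial and 10.7 and 8.89 M in the nucleolar pull-downs. The inputs held 11.3 M (non-transfected), 13.01 M (cytosolic), 6.34 M (nuclear) and 9.86 M (mitochondrial). A single read therefore stood for 0.0541 to 0.154 CPM, the deposited unit of level, and 3 reads for 0.162 to 0.461 CPM. Levels are mean CPM ± SD. Changes are log2 fold changes ± standard error on the log2(CPM + 1) scale, which understates the change of genes near or below 1 CPM. The labels call the replicates biological but name no separate cultures, so p-values measure the spread between these libraries, which may be technical. HSPA1B, EEF1A1, histone and zinc finger mRNAs have near-identical copies, and antisense genes overlap their partners, so how reads were divided among them is uncertain.

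The first question was which RNAs the cytosolic esterase marks over background (2 cytosolic against 3 non-transfected pull-downs). The largest rises belonged to genes that were low in the non-transfected pull-downs. LHFPL3-AS1, an antisense long non-coding RNA (lncRNA; chromosome 7, 104738597 to 104804107), stood at 1362 ± 30.8 CPM against 0.950 ± 0.928, a change of 9.56 ± 0.243 (limma adjusted p = 1.86e-13). SPATA9, a spermatogenesis gene (chromosome 5, 95652181 to 95698711), changed by 9.47 ± 0.289 (limma adjusted p = 1.66e-12). GMIP (chromosome 19, 19629476 to 19643667) reached 3961 ± 1.31 CPM against 6.80 ± 4.47, a change of 9.13 ± 0.291, and the potassium channel gene KCNT2 (chromosome 1, 196225779 to 196609225) changed by 8.39 ± 0.161. Inputs showed this too: GMIP was at 1504 CPM in the cytosolic and at 7.93 CPM in the non-transfected input. SPATA9 was at 9.49 CPM in the non-transfected input and at 1052, 1153 and 645 CPM in the cytosolic, nuclear and mitochondrial inputs. Among the largest falls were NPFFR1, a neuropeptide receptor gene (chromosome 10, 70247329 to 70283676), at -5.09 ± 0.664 (limma adjusted p = 1.65e-05), and TAL1, a blood-lineage transcription factor gene, at -3.35 ± 0.463. Both varied widely between the non-transfected pull-downs (102 ± 59.7 and 45.0 ± 30.4 CPM).

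Of 82 cytosolic ribosomal protein mRNAs, 80 fell (80 adjusted over the list alone), with a median of -1.02 (camera adjusted p = 3.94e-35, adjusted p = 0.305 with an estimated correlation). RPS29 (chromosome 14, 49570984 to 49599164) changed at -1.58 ± 0.127. Of 23 housekeeping mRNAs, 21 fell (22 adjusted over the list alone; camera adjusted p = 2.56e-11, adjusted p = 0.305 with an estimated correlation), among them that of the lactate dehydrogenase subunit LDHA (-0.89 ± 0.0838). The mRNA of the translation elongation factor EEF1A1 (chromosome 6, 73515750 to 73523797) fell too (-1.13 ± 0.0877). Its change was 0 under quantile normalization, which gives a gene that keeps its rank the same value in every library. That 0 is therefore no test of the fall. Among 81 nuclear-encoded subunits of oxidative phosphorylation, 75 fell, including COX7A2 (-1.35 ± 0.123), and 1 rose (1 and 75 adjusted over the list alone; camera adjusted p = 9.04e-23, adjusted p = 0.305 with an estimated correlation). The exception was COX7A2L, a respiratory supercomplex assembly gene (chromosome 2, 42333546 to 42425088), at 3.96 ± 0.0955. All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; camera adjusted p = 1.46e-08, adjusted p = 0.305 with an estimated correlation), from MT-ND6 (-1.80 ± 0.190) and MT-CO3 (-1.38 ± 0.143), which encode respiratory chain subunits. Their mean in the cytosolic input was already at -1.21 log2 against the non-transfected input. The input-corrected mean change was -0.0275 ± 0.374 (95% interval -0.912 to 0.857). Of 30 endoplasmic reticulum (ER) and secretory mRNAs, 22 fell and 2 rose (2 and 23 adjusted over the list alone; camera adjusted p = 2.92e-06, adjusted p = 0.305 with an estimated correlation), and APP, the amyloid precursor gene, changed at -0.84 ± 0.0769.

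Of 448 ZNF zinc finger mRNAs, 292 rose and 18 fell (304 and 19 adjusted over the list alone; camera adjusted p = 9.96e-15, adjusted p = 0.263 with an estimated correlation), with ZNF79 at 3.08 ± 0.102. Among 29 replication-dependent histone mRNAs, 15 rose (15 adjusted over the list alone; camera adjusted p = 1.18e-05, adjusted p = 0.169 with an estimated correlation), as H3C6 did (2.13 ± 0.121). Of 20 mRNAs known for detained introns, 10 rose and 5 fell (10 and 6 adjusted over the list alone; camera adjusted p = 0.0405, adjusted p = 0.572 with an estimated correlation). CCNL1, a cyclin of the splicing machinery, changed by 1.86 ± 0.112 and NKTR by 1.79 ± 0.103. Of 26 immediate-early and short-lived mRNAs, 16 rose and 4 fell (17 and 5 adjusted over the list alone; camera adjusted p = 0.00174, adjusted p = 0.448 with an estimated correlation), with the transcription factor gene EGR1 at 2.09 ± 0.148 and the antiproliferative gene BTG2 at 1.87 ± 0.0805. The stress phosphatase subunit PPP1R15A rose (2.34 ± 0.104) and the cystine transporter SLC7A11 fell (-1.60 ± 0.122). In that stress-response list of 18, 3 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.0513). NEAT1, a nuclear lncRNA of paraspeckles (chromosome 11, 65422774 to 65445540), fell (-0.80 ± 0.130), whereas MALAT1, of nuclear speckles (chromosome 11, 65497688 to 65506516), was at -0.11 ± 0.128 and did not pass (limma adjusted p = 0.492); it was 0.01 under quantile normalization and 0.05 with the length and GC trend removed.

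In all, limma called 4661 of 16133 genes higher and 3618 lower, 1053 and 561 of them by at least 2-fold. Among 78 mitoribosomal protein mRNAs, 41 fell and 5 rose (5 and 41 adjusted over the list alone; camera adjusted p = 1.95e-06, adjusted p = 0.548 with an estimated correlation), but 24 fell without cytosolic replicate 2. The nucleolar protein mRNAs gave 11 rises, NOP58 among them (0.82 ± 0.0910), and 2 falls, one of them FBL (-0.67 ± 0.110), of 24 (camera adjusted p = 0.0939). Heat shock genes went both ways, from BAG3 (1.16 ± 0.0913) to HSPB1 (-1.06 ± 0.211).

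**Figure D1:**
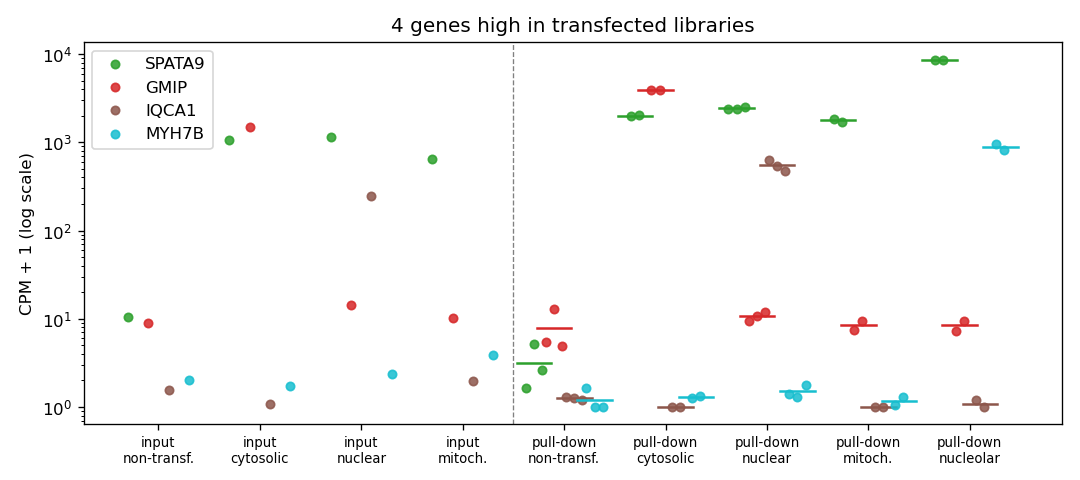
CPM + 1 (log scale) of SPATA9, GMIP, IQCA1 and MYH7B in each library, with 1 point per library, grouped by input (left of the dashed line) and pull-down (right). SPATA9 is at 645 CPM or more in every transfected library and at 9.49 CPM or less in non-transfected ones, while GMIP, IQCA1 and MYH7B are high with 1 construct each: GMIP at 3960.1 and 3962 CPM in the cytosolic pull-downs, IQCA1 at 631, 545 and 469 CPM in the nuclear ones and MYH7B at 948 and 825 CPM in the nucleolar ones.

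The second comparison asked the same of the nucleus (3 nuclear against 3 non-transfected pull-downs). MALAT1 went from 505 ± 69.7 to 1573 ± 238 CPM, a change of 1.64 ± 0.114 (limma adjusted p = 1.06e-08), and NEAT1 from 93.8 ± 15.5 to 222 ± 8.35 CPM, a change of 1.25 ± 0.116 (limma adjusted p = 2.17e-07). Of 12 nuclear-retained lncRNAs, 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0324, adjusted p = 0.323 with an estimated correlation). mRNAs with detained introns rose as well, 17 of 20, with 1 fall (17 and 1 adjusted over the list alone; camera adjusted p = 8.61e-07, adjusted p = 0.323 with an estimated correlation). Examples were CCNL1 (2.50 ± 0.0998) and the splicing kinase gene CLK1 (2.29 ± 0.0946). Among the largest rises were again LHFPL3-AS1 (9.99 ± 0.218), SPATA9 (9.76 ± 0.258) and KCNT2 (8.79 ± 0.144). They were joined by IQCA1, an ATPase-domain gene (chromosome 2, 236324147 to 236507542) that was at 548 ± 81.2 CPM with the nuclear construct and at 0.261 ± 0.0535 without transfection. IQCA1 was at 246 CPM in the nuclear input.

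Of 82 ribosomal protein mRNAs, 81 fell and 1 rose (1 and 81 adjusted over the list alone; camera adjusted p = 2.87e-32, adjusted p = 0.323 with an estimated correlation), with a median of -1.67 and RPL39 at -2.36 ± 0.0988. All 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 5.63e-13, adjusted p = 0.323 with an estimated correlation), EEF1A1 at -1.95 ± 0.0784. Among oxidative phosphorylation subunits 78 of 81 fell and 1 rose (1 and 78 adjusted over the list alone; camera adjusted p = 3.10e-20, adjusted p = 0.323 with an estimated correlation), with the ATP synthase subunit ATP5MF at -1.81 ± 0.112. Of 78 mitoribosomal mRNAs 66 fell and 2 rose (2 and 66 adjusted over the list alone; camera adjusted p = 4.54e-10, adjusted p = 0.380 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; camera adjusted p = 5.33e-07, adjusted p = 0.323 with an estimated correlation), from MT-ATP8 (-2.10 ± 0.178) and MT-ND6 (-1.83 ± 0.1699). Of 30 ER and secretory mRNAs 28 fell and 1 rose (1 and 28 adjusted over the list alone; camera adjusted p = 1.47e-09, adjusted p = 0.323 with an estimated correlation), APP at -1.36 ± 0.0688. MYC, the growth-promoting transcription factor gene, fell (-2.31 ± 0.0826) while FOSB rose (2.17 ± 0.182), in a list of 26 short-lived mRNAs with 17 rises and 7 falls (17 and 7 adjusted over the list alone; camera adjusted p = 0.00402, adjusted p = 0.419 with an estimated correlation).

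ZNF mRNAs rose in 322 of 448 cases and fell in 33 (327 and 33 adjusted over the list alone; camera adjusted p = 9.46e-16, adjusted p = 0.227 with an estimated correlation), with ZNF79 at 3.00 ± 0.0908. Histone mRNAs rose in 21 of 29 (21 adjusted over the list alone; camera adjusted p = 1.59e-06, adjusted p = 0.114 with an estimated correlation), with H4C8 at 2.73 ± 0.167. NPM1, which encodes an abundant nucleolar chaperone, fell (-1.15 ± 0.0879). The nucleolar protein list split 5 higher and 7 lower of 24 (camera adjusted p = 0.864), a balance that turned under each of the 4 other scalings and without nuclear replicate 1 (7 higher, 6 lower). Heat shock genes gave 7 falls and 1 rise of 13 (1 and 7 adjusted over the list alone; camera adjusted p = 0.0318, adjusted p = 0.419 with an estimated correlation), but 5 falls and 6 rises under quantile normalization. HSPA1B was at -1.14 ± 0.104 and HSPE1, the mitochondrial chaperonin partner, at -1.31 ± 0.0995.

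Limma called 5194 genes higher and 5511 lower of 16133, with 1608 and 1307 changed at least 2-fold. Rescaling every library to a common total gave 7235 higher and 3652 lower genes, and 7108 and 3767 without mitochondrially encoded genes in the total. The median of all genes moved from -0.03 to 0.22 and 0.20, and list medians above are relative to -0.03. The nuclear libraries differed among themselves: replicates 1 and 3 by a median of 0.253 log2, where replicate 1 and the mitochondrial pull-downs differed by 0.217 and 0.208. The lists seen in few genes gave little: 2 of 4 small nucleolar and small Cajal body RNAs rose, 1 of 2 spliceosomal small nuclear RNAs rose, and none of 2 nucleolar and polymerase III RNAs passed limma (1 at an unadjusted p under 0.05). Interferon genes gave 4 rises and 9 falls of 14 (camera adjusted p = 0.292), cytosolic lncRNAs 4 and 7 of 12 (camera adjusted p = 0.693) and stress-response genes 3 and 9 of 18 (camera adjusted p = 0.0976). Markers of blood cells, fibroblasts and keratinocytes, which HEK293T cells should lack, gave 2 rises and 3 falls among the 6 measured (camera adjusted p = 0.575).

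**Figure D2:**
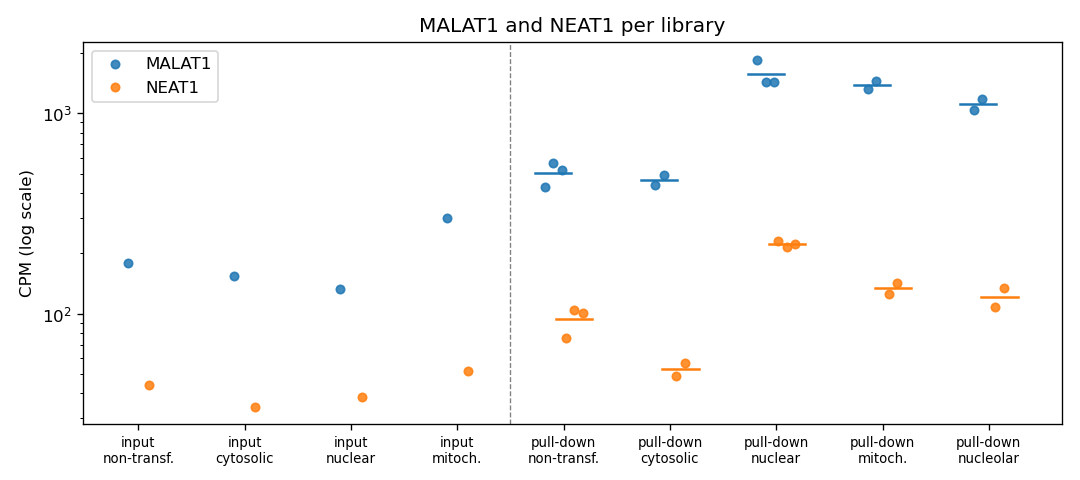
CPM (log scale) of MALAT1 and NEAT1 in each library, with 1 point per library, grouped by input (left of the dashed line) and pull-down (right). MALAT1 lies between 1435 and 1849 CPM in the nuclear pull-downs and between 428 and 564 CPM in the non-transfected and cytosolic ones. It is at 1322 and 1443 CPM in the mitochondrial pull-downs, which reaches the nuclear range, and at 1040 and 1176 CPM in the nucleolar ones.

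The third comparison asked what the mitochondrial esterase marks (2 mitochondrial against 3 non-transfected pull-downs). All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; camera adjusted p = 1.10e-07, adjusted p = 0.316 with an estimated correlation). MT-ND6 (chromosome M, 14149 to 14673) changed by 2.05 ± 0.190 (limma adjusted p = 4.50e-07), MT-ND1 by 2.04 ± 0.153 and MT-CO1 (chromosome M, 5904 to 7445) by 1.34 ± 0.122, from 4804 ± 381 to 12150.3 ± 516 CPM. The ribosomal RNA MT-RNR2 changed by 1.95 ± 0.149, and all 4 mitochondrial ribosomal and transfer RNAs measured rose (4 adjusted over the list alone; camera adjusted p = 0.00444, adjusted p = 0.228 with an estimated correlation). The 13 mRNAs made up 5.45 ± 0.862% of CPM in the mitochondrial pull-downs (SD, n = 2), 2.03 ± 0.236% in the non-transfected (n = 3), 0.888 ± 0.0607% in the cytosolic (n = 2), 0.876 ± 0.139% in the nuclear (n = 3) and 2.94 ± 0.498% in the nucleolar ones (n = 2). They also differed between the inputs, at 1.33% without transfection, 0.602% cytosolic, 1.84% nuclear and 3.29% mitochondrial. Their mean log2 level was 1.49 ± 0.203 higher than in the non-transfected pull-downs (95% interval 1.01 to 1.97).

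**Figure D3:**
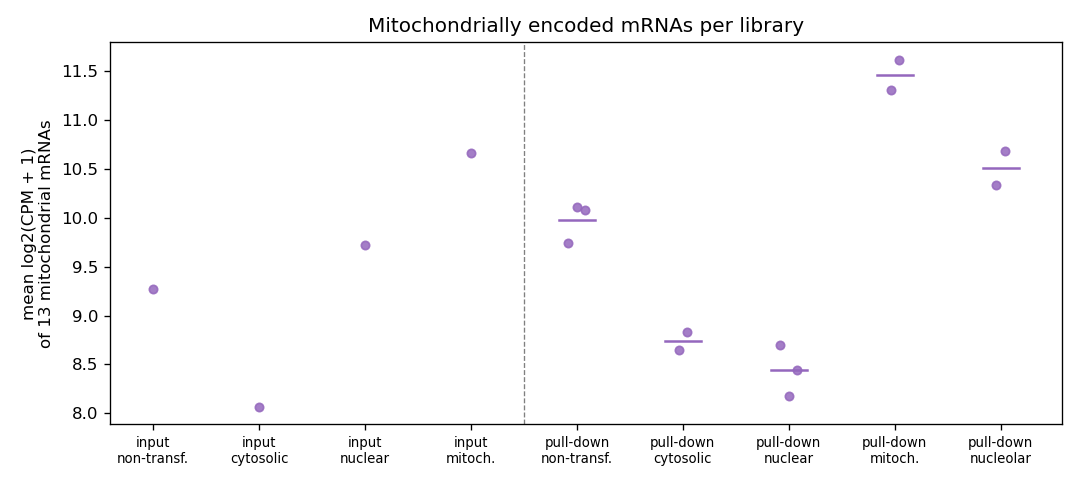
Mean log2(CPM + 1) of the 13 mitochondrially encoded mRNAs in each library, with 1 point per library, grouped by input (left of the dashed line) and pull-down (right). The mitochondrial pull-downs are at 11.31 and 11.62, above every other pull-down, and the mitochondrial input at 10.67 is the highest of the 4 inputs.

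Nuclear-encoded mRNAs of mitochondrial proteins did not follow: 76 of 81 oxidative phosphorylation subunits fell and 1 rose (1 and 76 adjusted over the list alone; camera adjusted p = 3.79e-23, adjusted p = 0.228 with an estimated correlation), with the ATP synthase subunit ATP5MC1 at -1.84 ± 0.124. Of 78 mitoribosomal mRNAs 52 fell, MRPL41 at -1.59 ± 0.204, and 4 rose (5 and 53 adjusted over the list alone; camera adjusted p = 8.30e-09, adjusted p = 0.400 with an estimated correlation). Ribosomal protein mRNAs fell in 80 of 82 cases (1 and 80 adjusted over the list alone for rises and falls; camera adjusted p = 4.44e-36, adjusted p = 0.228 with an estimated correlation), RPS29 at -2.01 ± 0.127. All 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 2.10e-13, adjusted p = 0.228 with an estimated correlation), EEF1A1 at -1.43 ± 0.0877 and the glycolytic GAPDH at -1.32 ± 0.119. Of 30 ER and secretory mRNAs 22 fell (23 adjusted over the list alone; camera adjusted p = 1.10e-07, adjusted p = 0.228 with an estimated correlation), SSR4 of the translocon at -1.32 ± 0.145. The stress-response list gave 11 falls and 3 rises of 18 (3 and 11 adjusted over the list alone; camera adjusted p = 0.0216, adjusted p = 0.341 with an estimated correlation), among the rises PPP1R15A (2.25 ± 0.104).

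MALAT1 rose (1.46 ± 0.128), and NEAT1 rose (0.52 ± 0.130, limma adjusted p = 0.00344) but lost its call without mitochondrial replicate 2, at 0.43. MALAT1 was at 301 CPM in the mitochondrial and 179 CPM in the non-transfected input, and NEAT1 at 51.8 and 43.8 CPM. ZNF mRNAs rose in 298 of 448 cases and fell in 23 (303 and 23 adjusted over the list alone; camera adjusted p = 3.54e-17, adjusted p = 0.187 with an estimated correlation), with ZNF79 at 3.08 ± 0.102. Histones rose in 16 of 29 (16 adjusted over the list alone; camera adjusted p = 2.09e-05, adjusted p = 0.187 with an estimated correlation), H2BC15 by 2.31 ± 0.136. Detained-intron mRNAs rose in 13 of 20 and fell in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 4.19e-05, adjusted p = 0.364 with an estimated correlation), CCNL1 by 2.34 ± 0.112. MYC fell (-1.98 ± 0.0923) within a short-lived list of 16 rises and 5 falls of 26 (16 and 5 adjusted over the list alone; camera adjusted p = 0.0144, adjusted p = 0.471 with an estimated correlation), and the small heat shock gene HSPB1 fell (-1.65 ± 0.211). The transfection-linked genes SPATA9 (9.30 ± 0.289), KCNT2 (7.71 ± 0.161) and the hexokinase-like HKDC1 (8.78 ± 0.184) rose again, and NPFFR1 (-3.71 ± 0.664) and TAL1 (-2.83 ± 0.463) fell. Limma called 4660 genes higher and 4359 lower of 16133, and 1239 and 874 changed at least 2-fold.

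The fourth comparison set 2 nucleolar against 3 non-transfected pull-downs. PPP1R15A went from 16.5 ± 2.05 to 263 ± 1.59 CPM, a change of 3.92 ± 0.104 (limma adjusted p = 1.42e-13), and the stress transcription factor DDIT3 changed by 1.99 ± 0.125. The AP-1 gene FOSL1 (3.48 ± 0.175) and BTG2 (2.701 ± 0.0805) rose among 17 rises and 5 falls of 26 short-lived mRNAs (17 and 5 adjusted over the list alone; camera adjusted p = 3.35e-04, adjusted p = 0.429 with an estimated correlation). Other stress-list members fell, SLC7A11 at -2.06 ± 0.122 and the serine synthesis gene PSAT1 at -1.84 ± 0.0760, so that list split 3 higher and 8 lower of 18 (4 and 8 adjusted over the list alone; camera adjusted p = 0.177). Of 29 histone mRNAs 22 rose (22 adjusted over the list alone; camera adjusted p = 1.84e-08, adjusted p = 0.0470 with an estimated correlation), H2AC6 by 3.82 ± 0.181. The box C/D protein NOP58 rose (1.68 ± 0.0910) and its partner FBL fell (-1.20 ± 0.110), within 11 rises and 5 falls of 24 nucleolar protein mRNAs (11 and 5 adjusted over the list alone; camera adjusted p = 0.113).

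Among the largest rises were HKDC1 by 11.81 ± 0.184, SPATA9 by 11.58 ± 0.289 and KCNT2 by 9.70 ± 0.161. MYH7B, a myosin heavy chain gene (chromosome 20, 34975403 to 35002437), was at 886 ± 86.8 CPM against 0.209 ± 0.361 (9.56 ± 0.231), and OSTM1-AS1 changed by 8.31 ± 0.190. NPFFR1 fell (-5.70 ± 0.664). CCNL1 (3.08 ± 0.112) and CLK1 (2.61 ± 0.106) rose with 15 of 20 detained-intron mRNAs, against 2 falls (15 and 2 adjusted over the list alone; camera adjusted p = 6.02e-06, adjusted p = 0.411 with an estimated correlation), and MALAT1 rose (1.14 ± 0.128). ZNF mRNAs rose in 303 of 448 cases and fell in 42 (304 and 45 adjusted over the list alone; camera adjusted p = 5.83e-16, adjusted p = 0.215 with an estimated correlation).

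Ribosomal protein mRNAs fell in 80 of 82 cases (81 adjusted over the list alone; camera adjusted p = 1.31e-24, adjusted p = 0.411 with an estimated correlation), RPL39 at -2.29 ± 0.110, and all 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 1.66e-09, adjusted p = 0.411 with an estimated correlation), EEF1A1 at -1.96 ± 0.0877. Of 81 oxidative phosphorylation subunits 74 fell, NDUFA4 at -2.16 ± 0.133, and 1 rose (1 and 74 adjusted over the list alone; camera adjusted p = 1.26e-15, adjusted p = 0.411 with an estimated correlation). Mitoribosomal mRNAs fell in 48 of 78 and rose in 11 (12 and 49 adjusted over the list alone; camera adjusted p = 0.00141, adjusted p = 0.656 with an estimated correlation). ER and secretory mRNAs fell in 25 of 30 (26 adjusted over the list alone; camera adjusted p = 3.41e-08, adjusted p = 0.411 with an estimated correlation), with the transferrin receptor TFRC at -1.27 ± 0.0916. Mitochondrially encoded mRNAs rose in 9 of 13 (9 adjusted over the list alone; camera adjusted p = 0.0348, adjusted p = 0.656 with an estimated correlation), MT-ND1 by 1.39 ± 0.153 and MT-ATP8 by 1.20 ± 0.199, but 3 rose without nucleolar replicate 2. Limma called 4857 genes higher and 5743 lower of 16133, 1869 and 1740 by at least 2-fold.

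**Figure D4:**
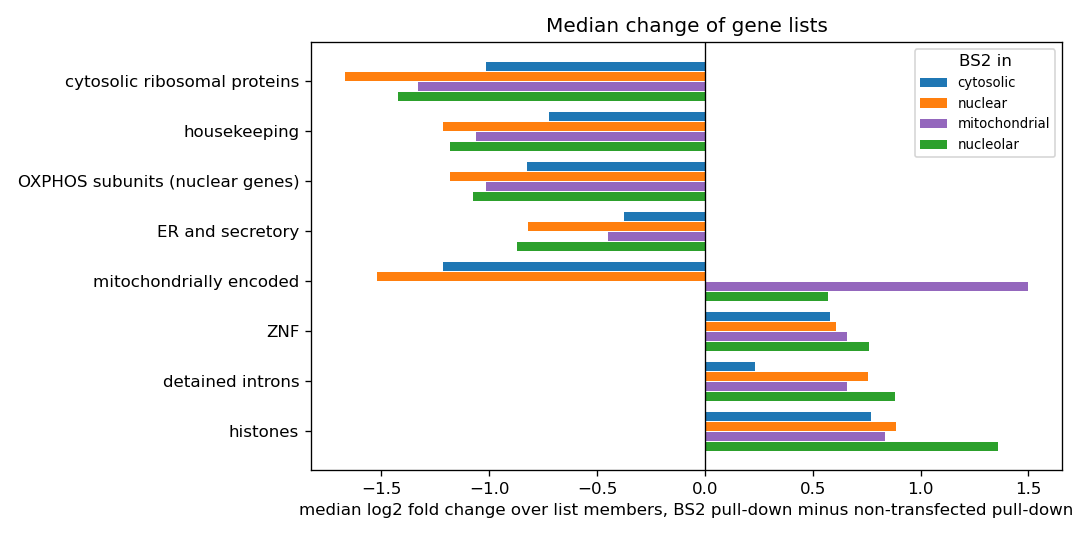
Median log2 fold change over the members of 8 gene lists in the cytosolic, nuclear, mitochondrial and nucleolar BS2 pull-downs against the non-transfected pull-downs, with 1 bar per construct and bars starting at 0. Ribosomal protein medians run from -1.02 to -1.67, and mitochondrially encoded mRNAs stand at 1.498 with the mitochondrial construct and at -1.52 with the nuclear one; none of the 8 lists turned its balance of calls in these comparisons under another scaling.

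Calls were widely shared by the 4 constructs: 3008 genes were higher in all 4 comparisons with the non-transfected pull-downs and 2649 were lower in all 4. Cytosolic and mitochondrial calls shared 3952 higher genes, where independent lists would share 1346, and 3062 lower genes, where they would share 978. Nuclear and nucleolar calls shared 3754 higher (1564 if independent) and 4391 lower genes (1962 if independent). Correlations of fold changes across genes ran from 0.835 to 0.904, against 0.400 to 0.447 in 50 simulations of unchanged groups with the same controls, and genes are not independent replicates. Covariances ran from 0.471 to 0.666 against 0.0142 to 0.0144 simulated. The 3 control libraries were not split, so part of the sharing could come from them. All 4 constructs were transfected and the controls were not, so effects of transfection cannot be told apart from labelling in these shared calls. The simulations do not cover transfection. Against the non-transfected input, ribosomal protein medians were -0.36, -0.30 and -0.41 log2 in the cytosolic, nuclear and mitochondrial inputs. Those of short-lived mRNAs were 0.44, 0.49 and 0.33. Genes at least 32-fold higher numbered 19 with the cytosolic, 22 with the nuclear, 18 with the mitochondrial and 30 with the nucleolar construct, 37 in any and 15 in all 4.

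Nuclear and cytosolic pull-downs were then compared directly (3 against 2), which sets 2 compartments against each other without the background samples. NEAT1 rose from 53.0 ± 5.55 to 222 ± 8.35 CPM (2.05 ± 0.130, limma adjusted p = 1.21e-07) and MALAT1 from 465 ± 36.4 to 1573 ± 238 CPM (1.75 ± 0.128, limma adjusted p = 4.95e-07). The microRNA host genes MIR34AHG (3.60 ± 0.186), MIR503HG (2.78 ± 0.213) and MIR17HG (2.62 ± 0.224) rose. Of 12 nuclear lncRNAs 7 rose (7 and 1 adjusted over the list alone for rises and falls; camera adjusted p = 1.13e-05, adjusted p = 0.228 with an estimated correlation), but 4 without cytosolic replicate 2. Detained-intron mRNAs rose in 10 of 20 and fell in 2 (12 and 3 adjusted over the list alone; camera adjusted p = 4.50e-08, adjusted p = 0.264 with an estimated correlation), the cyclin CCNL2 by 2.04 ± 0.108 and the glycosyltransferase OGT by 1.36 ± 0.0947. GAS5 (0.92 ± 0.0881) and SNHG1 (0.92 ± 0.0845), small nucleolar RNA hosts placed in the cytosolic lncRNA list, rose, but the list had 2 rises and 6 falls of 12 (2 and 6 adjusted over the list alone; camera adjusted p = 0.676), with 3 falls without cytosolic replicate 1, cytosolic replicate 2 or nuclear replicate 2. IQCA1 was at 548 ± 81.2 CPM and at 0 in both cytosolic libraries, at least 1983-fold higher against a floor of 3 reads. GMIP (-8.52 ± 0.291) and EXTL3, a heparan sulfate glycosyltransferase gene (-4.13 ± 0.0983), fell. The inputs differed in the same directions. IQCA1 was at 246 CPM in the nuclear and 0.0759 CPM in the cytosolic input, and GMIP at 13.4 and 1504 CPM. For IQCA1 and GMIP, compartment thus cannot be told apart from the starting RNA.

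Ribosomal protein mRNAs fell in 77 of 82 cases (78 adjusted over the list alone; camera adjusted p = 1.90e-23, adjusted p = 0.268 with an estimated correlation), RPS27 at -1.03 ± 0.112, and all 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 4.43e-11, adjusted p = 0.264 with an estimated correlation), EEF1A1 at -0.82 ± 0.0877. Heat shock genes fell in 12 of 13 (12 adjusted over the list alone; camera adjusted p = 1.13e-05, adjusted p = 0.264 with an estimated correlation), HSPA8, the constitutive HSP70 (chromosome 11, 123057489 to 123063230), at -0.68 ± 0.0791 and HSPA1B at -0.87 ± 0.116. ER and secretory mRNAs fell in 19 of 30 (21 adjusted over the list alone; camera adjusted p = 1.36e-07, adjusted p = 0.264 with an estimated correlation), the ER chaperones HSPA5 at -0.61 ± 0.0873 and CANX at -0.57 ± 0.1005. Of 24 nucleolar protein mRNAs 12 fell and 1 rose (1 and 15 adjusted over the list alone; camera adjusted p = 0.00224, adjusted p = 0.268 with an estimated correlation), NPM1 at -0.68 ± 0.0983 and NCL at -0.65 ± 0.0939, but 7 fell without cytosolic replicate 1. The cytosolic and nuclear inputs, 1 library each, also differed in the share of CPM of these lists. It was 1.14% and 0.982% for heat shock genes and 1.12% and 1.04% for ER and secretory mRNAs. Nucleolar protein mRNAs were at 1.06% and 0.928%, ribosomal protein mRNAs at 9.23% and 9.49% and housekeeping mRNAs at 4.03% and 4.01%. For heat shock, ER and nucleolar protein mRNAs, compartment was thus not told apart from the starting RNA. IRS4, an insulin signalling adaptor (-1.08 ± 0.106), and IGFBP5, which binds insulin-like growth factors (-1.07 ± 0.0921), fell. Limma called 1640 genes higher and 3747 lower of 16133, 5387 in all, and 440 and 27 by at least 2-fold. Without cytosolic replicate 1 it called 2756 and without replicate 2 it called 2269. The balance depended on scaling, with 3036 higher and 936 lower after rescaling to a common total, 3029 and 942 when mitochondrially encoded genes were left out of the total, 2068 and 2356 with median-of-ratios factors, and 1788 and 1708 after quantile normalization. The median of all genes moved from -0.12 to 0.10 on rescaling.

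Mitochondrial against cytosolic pull-downs (2 against 2) were compared next. All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; camera adjusted p = 1.24e-59, adjusted p = 0.0119 with an estimated correlation): MT-ND6 by 3.85 ± 0.208 (limma adjusted p = 3.35e-08), MT-ND2 by 2.96 ± 0.179, MT-ND4 by 2.81 ± 0.181 and MT-ND1 by 2.80 ± 0.167. Their mean was 2.73 ± 0.222 higher (95% interval 2.20 to 3.25), but the inputs differed alike, at 1.39 and -1.21 against the non-transfected input. With input correction the difference was 0.123 ± 0.385 (-0.787 to 1.03). All 4 mitochondrial ribosomal and transfer RNAs rose (4 adjusted over the list alone; camera adjusted p = 3.05e-13, adjusted p = 0.0119 with an estimated correlation), MT-RNR2 by 2.42 ± 0.163. MALAT1 (1.57 ± 0.140) and NEAT1 (1.32 ± 0.142) rose, the called members (2) of 12 nuclear lncRNAs (4 adjusted over the list alone; camera adjusted p = 1.81e-06, adjusted p = 0.0513 with an estimated correlation). CCNL2 rose (0.84 ± 0.119). GMIP fell (-8.88 ± 0.318), as did EXTL3 (-4.36 ± 0.108). GMIP also differed between the inputs, at 9.28 CPM in the mitochondrial and 1504 CPM in the cytosolic one. So did MALAT1, at 301 and 154 CPM, and NEAT1, at 51.8 and 34.2 CPM, in the same order. For these genes, labelling was thus not told apart from the starting RNA. Of 82 ribosomal protein mRNAs none passed over all genes while 44 fell adjusted over the list alone, with 50 at an unadjusted p under 0.05 (camera adjusted p = 2.36e-18, adjusted p = 0.406 with an estimated correlation).

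Limma called 102 genes higher and 32 lower of 16133, 134 in all, and 67 and 9 by at least 2-fold; 2560 genes had an unadjusted p under 0.05. Single libraries moved this count: 39 without cytosolic replicate 1, 61 without cytosolic replicate 2, 85 without mitochondrial replicate 1 and 46 without mitochondrial replicate 2. It was 299 without nuclear replicate 1 and 687 without nuclear replicate 3, which enter through the shared spread. The total was 1301 in a fit of only these groups, 479 with replicate number as a block and 579 with the length and GC trend removed. Rescaling to a common total gave 105 higher and 58 lower genes. The smaller changes called here, in PNISR, MAP4, PRKDC, HSPA1B, PDIA4 and ZNF121, each lost their call without at least 1 of the cytosolic or mitochondrial libraries, so they are named only for that.

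Nucleolar and nuclear pull-downs (2 against 3) addressed whether the nucleolar tag reports RNAs apart from those of the whole nucleus. Chaperone mRNAs were higher with the nucleolar than with the nuclear construct. Of 13 heat shock genes 10 rose (10 adjusted over the list alone, camera adjusted p = 2.76e-07, adjusted p = 0.178 with an estimated correlation). HSPA8 went from 915 ± 23.2 to 1810.2 ± 28.95 CPM (0.98 ± 0.0791, limma adjusted p = 5.44e-07). DNAJA1 changed by 0.94 ± 0.0868 and the HSP90 cofactor CHORDC1 by 1.24 ± 0.136. The heat shock list made up 0.659 ± 0.0209% of CPM in the nuclear pull-downs, the lowest share of any pull-down group. It made up 0.921 ± 0.0122% in the nucleolar and 0.891 ± 0.0247% in the non-transfected pull-downs. Without a nucleolar input, differences in the starting RNA were not tested for any list here. Nucleolar protein mRNAs rose in 12 of 24 and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00204, adjusted p = 0.482 with an estimated correlation), NOP58 by 1.14 ± 0.0910 and NCL by 0.99 ± 0.0939. NPM1 was at 0.84 ± 0.0983, but at -0.06 under quantile normalization. PPP1R15A (1.88 ± 0.104), its regulator ATF4 (0.65 ± 0.0789) and JUN (1.000 ± 0.0892) rose. Of 18 stress-response genes 5 rose and 6 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.855), but 3 rose and 1 fell without nucleolar replicate 2. All 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; camera adjusted p = 1.32e-16, adjusted p = 0.178 with an estimated correlation), MT-ATP8 by 3.30 ± 0.199 and MT-ND1 by 2.41 ± 0.153. Histones rose in 13 of 29 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 6.81e-04, adjusted p = 0.178 with an estimated correlation), H2AC6 by 1.97 ± 0.181, but 6 rose without nucleolar replicate 1 and 5 without replicate 2.

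NEAT1 was lower with the nucleolar construct, at -0.88 ± 0.130, as were CCNL2 at -0.82 ± 0.108 and MALAT1 at -0.50 ± 0.128, whose call was lost without nucleolar replicate 1 (-0.41). Of 12 nuclear-retained lncRNAs 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.508). MYH7B (9.21 ± 0.231), OSTM1-AS1 (8.37 ± 0.190), the lncRNA HELLPAR (7.06 ± 0.168) and the separase gene ESPL1 (5.29 ± 0.115) rose, while IQCA1 (-8.96 ± 0.173) and the inflammasome gene NLRP6 (-2.48 ± 0.215) fell. IQCA1 was at 246 CPM in the nuclear input, and no nucleolar input was used. RPL26 (1.47 ± 0.0956) and PFN1 (1.30 ± 0.129) rose, but their lists turned direction under quantile normalization (18 ribosomal protein mRNAs higher and 23 lower, 4 housekeeping mRNAs higher and 11 lower). Limma called 2679 genes higher and 2888 lower of 16133, 5567 in all, and 366 and 237 by at least 2-fold. The total was 3675 without nucleolar replicate 1 and 3254 without replicate 2. Rescaling to a common total gave 1702 higher and 5563 lower genes, and 1863 and 5063 without mitochondrially encoded genes in the total, as the median of all genes moved from -0.05 to -0.22 and -0.19.

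Pull-down against input, with construct as a covariate (10 pull-downs and 4 inputs of the non-transfected, cytosolic, nuclear and mitochondrial cells), gave an average over these constructs. MALAT1 rose from 192 ± 75.05 to 993 ± 549.5 CPM (2.22 ± 0.231, limma adjusted p = 9.94e-07) and NEAT1 by 1.405 ± 0.196, and the cytosolic lncRNA NORAD rose too (0.96 ± 0.0859). Of 12 nuclear-retained lncRNAs 6 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.160). Of 12 cytosolic lncRNAs 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.423), but 5 rose and 4 fell with the length and GC trend removed, and 1 rose and 1 fell in the non-transfected libraries alone. SKIL (1.66 ± 0.142), SOCS4 (1.60 ± 0.154), FRS2 (1.60 ± 0.149) and TP53INP1 (1.71 ± 0.193) rose, with NKTR (1.39 ± 0.114) and PNISR (1.30 ± 0.129) among 15 rises of 20 detained-intron mRNAs (16 and 1 adjusted over the list alone for rises and falls; camera adjusted p = 0.00122, adjusted p = 0.499 with an estimated correlation). ZNF mRNAs rose in 315 of 449 cases and fell in 50 (316 and 51 adjusted over the list alone; camera adjusted p = 1.35e-09, adjusted p = 0.477 with an estimated correlation). SLC7A11 rose as well (1.31 ± 0.101).

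Of 81 oxidative phosphorylation subunits 75 fell and 3 rose (3 and 75 adjusted over the list alone; camera adjusted p = 3.74e-22, adjusted p = 0.477 with an estimated correlation), NDUFB7 at -2.31 ± 0.177 and ATP5F1D at -2.15 ± 0.164. Mitoribosomal mRNAs fell in 62 of 78 and rose in 3 (3 and 62 adjusted over the list alone; camera adjusted p = 2.34e-14, adjusted p = 0.477 with an estimated correlation). Ribosomal protein mRNAs fell in 79 of 82 (80 adjusted over the list alone; camera adjusted p = 4.01e-18, adjusted p = 0.499 with an estimated correlation), RPS15 at -1.82 ± 0.185, and all 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 8.01e-10, adjusted p = 0.477 with an estimated correlation), the glycolytic ALDOA at -1.49 ± 0.134 and TPI1 at -1.36 ± 0.123. The ribosome biogenesis gene BOP1 fell (-1.65 ± 0.136), as did MT-RNR1 (-1.09 ± 0.133), SVOP (-3.55 ± 0.338) and SNX31 (-3.40 ± 0.513). HSPA1B (-1.36 ± 0.196) and MYC (-1.13 ± 0.171) fell and KLF10 rose (1.28 ± 0.172). In the non-transfected libraries alone these last 3 and SNX31 did not pass (HSPA1B -0.21, MYC -0.16, KLF10 0.33, SNX31 -0.94). MT-ND5 (0.82 ± 0.278, limma adjusted p = 0.0160) lost its call without the non-transfected (0.66), the cytosolic (0.62) or the mitochondrial input (0.64). Limma called 6034 genes higher and 4835 lower of 16510, 853 and 1245 by at least 2-fold. In the non-transfected libraries alone it called 5336, against 10869 in all.

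Across 16317 genes with a length in the annotation, the change from input to pull-down followed transcript length (Spearman's rho 0.374) and GC content (rho -0.664), as a description over genes, which are not replicates. Transcripts in the lowest 25% by length had a median change of -0.27 and those in the highest 25% of 0.41. Against the non-transfected pull-downs the length rho was 0.266 for the cytosolic, 0.177 for the nuclear, 0.231 for the mitochondrial and 0.109 for the nucleolar construct. The GC rho was -0.167, 0.0241, -0.291 and -0.124 in the same order. Between constructs the GC rho was 0.289 for nuclear against cytosolic, -0.393 for mitochondrial against cytosolic and -0.279 for nucleolar against nuclear. Length and GC content were described for all 11 comparisons.

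The last question was which changes against non-transfected cells exceed those of the inputs, tested as the difference of pull-down minus input between construct and non-transfected cells. Each rests on 1 input per arm, assumed to vary like the pull-down replicates. For the nucleus (3 against 3 pull-downs), MALAT1 stayed up at 2.07 ± 0.229 (limma adjusted p = 1.77e-04), with inputs at 133 and 179 CPM, and NEAT1 at 1.43 ± 0.237. CLK1 (1.66 ± 0.192) and OGT (1.33 ± 0.169) rose among 10 detained-intron mRNAs of 20, with 1 fall (14 and 1 adjusted over the list alone; camera adjusted p = 3.78e-07, adjusted p = 0.201 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell (13 adjusted over the list alone; camera adjusted p = 1.79e-14, adjusted p = 0.167 with an estimated correlation), MT-ND6 at -2.82 ± 0.346 and MT-ATP8 at -2.51 ± 0.364. Ribosomal protein mRNAs fell in 77 of 82 (78 adjusted over the list alone; camera adjusted p = 9.80e-52, adjusted p = 0.167 with an estimated correlation), RPS29 at -2.01 ± 0.228, and all 23 housekeeping mRNAs fell (23 adjusted over the list alone; camera adjusted p = 4.05e-18, adjusted p = 0.167 with an estimated correlation), EEF1A1 at -1.47 ± 0.156. HSPA1B (-1.80 ± 0.210), HSPA5 (-1.14 ± 0.154), MYC (-1.52 ± 0.157) and NPM1 (-0.80 ± 0.175) fell; NPM1 lost its call under quantile normalization (-0.18). The input-corrected change was 2.98 ± 0.530 for SPATA9 and 2.88 ± 0.203 for the cadherin CDH13. Nuclear pull-down minus nuclear input was 1.08 and 0.927 for these genes. The remainder came from the non-transfected cells, with SPATA9 at 9.49 CPM in the lone input and 0.626 to 4.20 CPM in the pull-downs. Limma called 1273 genes higher and 1492 lower of 16693, but 2596 and 961 after rescaling to a common total and 2393 and 1038 without mitochondrially encoded genes in the total, with the median of all genes at 0.16 and 0.14 in place of -0.01. The total of 2765 was 1385 in a fit of only the groups compared and 4365 with the length and GC trend removed.

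For the mitochondria (2 against 3 pull-downs), none of the mitochondrially encoded mRNAs was called beyond its input. Their input-corrected changes ran from -0.32 to 0.40 with a median of 0.11, and of 13 none passed limma, over all genes or adjusted over the list alone, nor at an unadjusted p under 0.05 (camera adjusted p = 0.807). MT-CO1 was at 0.40 ± 0.226 (limma adjusted p = 0.278), with 6413 CPM in the mitochondrial and 3331 CPM in the non-transfected input. Their mean change was 0.0952 ± 0.374 (95% interval -0.789 to 0.980). It was 2.08 ± 0.374 above that with the nuclear construct (1.20 to 2.97) and 0.123 ± 0.385 from that with the cytosolic one (-0.787 to 1.03). Ribosomal protein mRNAs fell in 69 of 82 (77 adjusted over the list alone; camera adjusted p = 2.26e-42, adjusted p = 0.327 with an estimated correlation), RPS29 at -1.45 ± 0.235, and 40 fell without mitochondrial replicate 2. COX6B1 (-1.31 ± 0.230), MYC (-1.49 ± 0.162) and HSPA1B (-1.38 ± 0.216) fell. CLK1 (1.22 ± 0.198), DDIT3 (1.34 ± 0.233), H2BC15 (1.98 ± 0.261) and CDH13 (3.77 ± 0.209) rose. For CDH13, mitochondrial pull-down minus mitochondrial input was 1.81, and the remainder came from the non-transfected cells. MALAT1 was at 0.71 ± 0.236 (limma adjusted p = 0.0703); the same change passed without nuclear replicate 1 or 3.

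Limma called 1028 genes higher and 567 lower of 16693, 1595 in all, for the mitochondria, and 925 and 821 under quantile normalization. The total was 933 without the trend and 2612 with the length and GC trend removed. It was 1047 without cytosolic replicate 1, 1048 without cytosolic replicate 2, 2700 without nuclear replicate 3, 940 without mitochondrial replicate 1 and 837 without mitochondrial replicate 2.

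For the cytosol (2 against 3 pull-downs), the chaperone genes HSPA1B (-1.48 ± 0.216, limma adjusted p = 0.00185) and HSPA5 (-0.83 ± 0.159) fell against their inputs. RPL27A fell (-0.996 ± 0.193), one of 37 falls among 82 ribosomal protein mRNAs (66 adjusted over the list alone; camera adjusted p = 1.37e-29, adjusted p = 0.430 with an estimated correlation). That list had 21 falls without non-transfected replicate 3, 11 without cytosolic replicate 1 and 3 without cytosolic replicate 2. RPS19 (-1.02 ± 0.252) and ENO1 (-0.75 ± 0.174) lost their calls without either cytosolic replicate (-1.08 and -0.78 without replicate 1, -0.96 and -0.72 without replicate 2). MT-ND6 (-1.85 ± 0.357) was the only fall among 13 mitochondrially encoded mRNAs, none of which rose (1 adjusted over the list alone; camera adjusted p = 0.696), and their mean change was -0.0275 ± 0.374 (95% interval -0.912 to 0.857). CCNL1 (1.12 ± 0.208), ZNF654 (2.04 ± 0.285) and KLF10 (1.34 ± 0.258) rose. Without cytosolic replicate 2, EGR1 (1.35 ± 0.278) and NPFFR1 (-5.65 ± 1.25) lost their calls at 1.31 and -5.57. Limma called 958 genes higher and 463 lower of 16693, 1421 in all. The totals were 567 without cytosolic replicate 1, 330 without cytosolic replicate 2, 2278 without nuclear replicate 1 and 2821 without nuclear replicate 3. Median-of-ratios scaling gave 855 higher and 666 lower genes, and quantile normalization 934 and 706. The total was 683 without the trend and 3031 in a fit of only the groups compared.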

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

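No test given here was chosen after the result was seen. The 3 counts below come from a test of the difference between construct and non-transfected cells in pull-down minus input, which flagged a difference between groups. The input-corrected differences were called for 1421 genes with the cytosolic, 2765 with the nuclear and 1595 with the mitochondrial construct. Each rests on 1 input per arm, and groups of at most 3 libraries were not tested for a library far from the others.

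Whether calls arise from other groupings was tested with a prediction written before the result was seen. For pull-down against input, 100 of 144 possible choices of a library per construct as the input were run. Only the real one gave as many calls (10869, with 7516 the highest other), so a chance choice of libraries can be excluded. Any other difference shared by the inputs would give the same result and was not tested. For nuclear against non-transfected there were only 10 splits of the 6 libraries, too few to exclude chance, with 10705 genes for the real split and 1 gene for the highest other.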

How the results depend on the processing

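Limits are depth (1 read is 0.0541 to 0.154 CPM), 2 libraries per group in 3 of 5 groups, and inputs of 1 library. Of the other values for the answers themselves, 373 stayed the same and 61 moved. For counts, the same meant within 1.5 times. For the rho of length with change, it meant within the largest shift from leaving out 1 library. For single genes, 19 results lost their call in 52 values and 1 gained it in 4. Where no cause is named, the cause was not tested. A test of counts (edgeR) was planned if whole reads could be recovered, and was not run because they could not.

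A minimum 2-fold change, which is stricter by construction, left 1614 for cytosolic against non-transfected, 2915 for nuclear against non-transfected, 2113 for mitochondrial against non-transfected, 3609 for nucleolar against non-transfected, 467 for nuclear against cytosolic, 76 for mitochondrial against cytosolic, 603 for nucleolar against nuclear, 2098 for pull-down against input, 633 for input-corrected cytosolic, 1197 for input-corrected nuclear and 761 for input-corrected mitochondrial. Counts moved by more than 1.5 times also under quantile normalization (3496 for nuclear against cytosolic), no trend (683 for input-corrected cytosolic and 933 for input-corrected mitochondrial), a fit of only the groups compared (1301 for mitochondrial against cytosolic, 3031 for input-corrected cytosolic and 1385 for input-corrected nuclear), non-transfected libraries only (5336 for pull-down against input) and the length and GC trend removed (579 for mitochondrial against cytosolic, 4365 for input-corrected nuclear and 2612 for input-corrected mitochondrial). The median rho of length with change over the 4 comparisons against non-transfected (0.204) was 0.226 under quantile normalization, 0.122 without a filter, 0.254 with a filter of 5 CPM and 0.0257 with the trend removed, as built.

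Leaving out 1 library at a time, where a lone library is assumed to vary like the others, gave totals of 5784 to 8910 for cytosolic against non-transfected, 9771 to 10627 for nuclear against non-transfected, 7059 to 9534 for mitochondrial against non-transfected, 8877 to 10983 for nucleolar against non-transfected, 2269 to 6081 for nuclear against cytosolic, 39 to 687 for mitochondrial against cytosolic, 3254 to 6099 for nucleolar against nuclear, 9864 to 11123 for pull-down against input, 330 to 2821 for input-corrected cytosolic, 2007 to 4092 for input-corrected nuclear and 837 to 2700 for input-corrected mitochondrial.

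Of 21 lists, camera calls with the preset correlation, with an estimated correlation and fry calls were 10, 0 and 15 for cytosolic against non-transfected, 12, 0 and 17 for nuclear against non-transfected, 12, 0 and 17 for mitochondrial against non-transfected, 10, 1 and 16 for nucleolar against non-transfected, 13, 0 and 13 for nuclear against cytosolic, 12, 2 and 4 for mitochondrial against cytosolic, 9, 0 and 7 for nucleolar against nuclear, 6, 0 and 13 for pull-down against input, 8, 0 and 3 for input-corrected cytosolic, 13, 0 and 14 for input-corrected nuclear and 9, 0 and 5 for input-corrected mitochondrial.

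The replicate numbers in the labels gave no clear pairing of the samples, and pairing was neither shown nor excluded. Correlations of same-numbered libraries, as deviations from their group mean, ran from -0.167 to 0.161 over 21 pairs, with 3 above 0.1. By the number in the library code they ran from -0.155 to 0.161 over 19 pairs. In groups of 2 libraries the deviations mirror each other, so some pairs repeat and are not separate checks. A block on replicate number gave 479 genes in place of 134 for mitochondrial against cytosolic, and moved no other count of genes by more than 1.5 times.

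Of single genes, MALAT1 changed sign in cytosolic against non-transfected (0.0084 under quantile normalization, 0.0508 with the length and GC trend removed). NCL in nuclear against non-transfected was 0.18 and NPM1 in nucleolar against nuclear was -0.0554 under quantile normalization. MT-ND5 in pull-down against input also lost its call with robust moderation, with a block by library code and with the length and GC trend removed. For mitochondrial against cytosolic, PNISR, PRKDC, MAP4, HSPA1B, PDIA4 and ZNF121 lost their calls under several settings.

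The balance of members called higher and lower turned for these lists, given as higher/lower. Under rescaling to a common total: nuclear against non-transfected, nucleolar proteins 15/3, and for nuclear against cytosolic, mitoribosomal proteins 4/3, stress response 5/0, interferon 2/0 and short-lived mRNAs 8/1, and for nucleolar against nuclear, oxidative phosphorylation 16/28, detained introns 4/9, ZNF 63/96 and housekeeping 4/8. Under median-of-ratios scaling: nuclear against non-transfected, nucleolar proteins 10/6, and for nuclear against cytosolic, stress response 2/0 and short-lived mRNAs 4/2, and for nucleolar against nuclear, ER and secretory 8/6, and for pull-down against input, short-lived mRNAs 8/11. Under rescaling without mitochondrially encoded genes: nuclear against non-transfected, nucleolar proteins 15/3, and for nuclear against cytosolic, mitoribosomal proteins 4/3, stress response 5/0, interferon 2/0 and short-lived mRNAs 8/1, and for nucleolar against nuclear, oxidative phosphorylation 18/25, detained introns 4/8, ZNF 74/85 and housekeeping 4/8. Under quantile normalization: cytosolic against non-transfected, cytosolic lncRNAs 3/5, and for nuclear against non-transfected, nucleolar proteins 12/6 and heat shock 6/5, and for nuclear against cytosolic, stress response 5/0 and short-lived mRNAs 7/3, and for nucleolar against nuclear, ribosomal proteins 18/23, detained introns 4/9 and housekeeping 4/11, and for pull-down against input, short-lived mRNAs 9/10, and for input-corrected nuclear, nucleolar proteins 3/2. Under no filter: nucleolar against nuclear, ER and secretory 7/6. Under no trend: nuclear against cytosolic, stress response 1/0, and for nucleolar against nuclear, ER and secretory 7/6. Under a fit of only the groups compared: nuclear against cytosolic, stress response 1/0, and for nucleolar against nuclear, ER and secretory 7/6. Under non-transfected libraries only: pull-down against input, nucleolar proteins 8/4, ER and secretory 11/5 and short-lived mRNAs 2/3. Under removal of the length and GC trend: cytosolic against non-transfected, cytosolic lncRNAs 3/4 and heat shock 5/6, and for nucleolar against nuclear, oxidative phosphorylation 22/25 and detained introns 6/7, and for pull-down against input, cytosolic lncRNAs 5/4, histones 12/4 and stress response 5/3.

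Leaving out 1 library turned the balance of some lists, with these ranges of members. Nucleolar proteins called lower in pull-down against input, 7 to 11 (turned without the nuclear input). ER and secretory called lower in nucleolar against nuclear, 4 to 9 (turned without cytosolic 1, cytosolic 2, nuclear 2 and nucleolar 2). Stress response called lower in nuclear against cytosolic, 0 to 7 (turned without cytosolic 2 and nuclear 2). Interferon called lower in nuclear against cytosolic, 0 to 3 (turned without cytosolic 2). Stress response called higher in input-corrected cytosolic, 0 to 4 (turned without cytosolic 2). Nucleolar proteins called lower in nuclear against non-transfected, 6 to 7 (turned without nuclear 1). ZNF called higher in nuclear against cytosolic, 20 to 65 (turned without nuclear 1). ZNF called higher in mitochondrial against cytosolic, 0 to 8 (turned without nuclear 3). Stress response called lower in nucleolar against nuclear, 1 to 8 (turned without nucleolar 2).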

Other observations

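All tests given here were chosen after the result was seen. The inputs themselves differed, in single libraries without replicates. In cytosolic, nuclear and mitochondrial order, medians against the non-transfected input were 0.44, 0.49 and 0.33 log2 for short-lived mRNAs, 0.41, 0.13 and 0.19 for heat shock genes, 0.37, 0.33 and 0.22 for nucleolar protein mRNAs and 0.54, 0.42 and 0.31 for histone mRNAs. Stress-response genes were at -0.23, -0.41 and -0.53 and ribosomal protein mRNAs at -0.36, -0.30 and -0.41. Oxidative phosphorylation subunits were at -0.35, -0.30 and -0.37, ZNF mRNAs at 0.16, 0.26 and 0.23 and detained-intron mRNAs at 0.17, 0.26 and 0.25. Among 10000 random lists of the same size and level the short-lived medians were at percentiles 100, 100 and 100, the heat shock medians at 100, 99.02 and 99.8 and the ribosomal protein medians at 0.01, 0.08 and 0, in the same order. Oxidative phosphorylation medians were at percentiles 0, 0 and 0, ZNF medians at 100, 100 and 100 and detained-intron medians at 98.97, 99.96 and 99.99. These percentiles measure no spread between libraries. All 3 differences share the same single non-transfected input, so they are not independent. Of 15090 genes, 121 were at least 4-fold higher and 29 lower in the cytosolic input, 141 and 22 in the nuclear and 89 and 36 in the mitochondrial one. In all, 246 genes were at least 4-fold higher in any of the 3.

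Genes at least 32-fold higher with a construct were picked by pull-down level. For the cytosolic, nuclear and mitochondrial constructs, labelling with no change in the starting RNA is excluded for the group: the median rise in the transfected inputs was 5.08 log2, and 59 of 59 gene and construct pairs rose by more than 2. Reads of a shared source, such as the plasmid, were left open. The members' spread of pull-down to input ratios was below that of most random lists of like input level (highest percentile 0.42 over 3 constructs), but choosing members by pull-down level can narrow it by itself. Neither test covers the nucleolar construct, which has no input.

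For the 13 mitochondrially encoded mRNAs in mitochondrial pull-downs, more of this RNA in the starting material could explain the rise. The input-corrected mean change was 0.0952 log2, where the pull-down change was 1.49. Labelling in mitochondria beyond the starting RNA was neither shown nor excluded, since the interval reached 0.980. Both tests lean on 1 input library per construct.

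For ribosomal protein mRNAs, a trend with annotated length and GC content did not account for the whole fall. With that trend removed, at least 79 of 82 were still called lower. Annotated values were medians over a gene's transcripts and need not match the form expressed. Effects of the expressed form's length or GC content are therefore not excluded. Medians were -0.81, -1.39, -1.13 and -1.26 after removal for the cytosolic, nuclear, mitochondrial and nucleolar constructs. Less of this RNA in the starting material could not be settled. The highest upper end of the intervals of the input-corrected means was -0.151, below 0, but it leans on 1 non-transfected input shared by the 3 constructs.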
